A study of Rattus norvegicus with 35 samples.

How the data were processed

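The series holds 35 single-colour Affymetrix 3 prime arrays of liver RNA from male Harlan Sprague Dawley rats, 1 array per rat, in 6 groups given BTBPE or corn oil by gavage at 5 ml/kg body weight. Per the labels' protocols, RNA with an integrity number of at least 7.0 was used, and 100 ng per sample was amplified and labelled with biotin. The samples were assigned to dose groups from their labels. Per the submitters' processing notes the arrays were processed with RMA and the affy package, whose versions are not given in the sources used here. The authors' deposited values were read as log2 RMA expression per probe set. They ran from 1.45 to 14.44 with array medians between 4.71 and 4.79, so they were not centred by gene, while the base of the logarithm is taken from RMA's convention.

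The deposited table listed 31099 probe sets. The 57 control probe sets of the array maker were left out, and the other 31042 were tested without a filter on dim signals. No further normalisation was applied. RMA's quantile step gives all arrays nearly the same distribution, so a shift of most transcripts in 1 direction would be reduced by it, and its background step compresses differences between dim probe sets. The number of arrays limits the precision, since a hybridisation signal has no read depth.

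Genes were named from the platform annotation, with symbols checked through gene identifiers against the RefSeq annotation of assembly GRCr8, used for names only. Of the tested probe sets 20826 had 1 gene symbol, 436 had several and 9780 had none, and 20758 of the first kind matched a current identifier, with 0 symbols changed. A probe set with several genes was not named, and listed genes without a probe set of 1 symbol were not analysed here. Each of 14217 genes was represented by the probe set with the highest mean over all arrays, and disagreement of another probe set in sign is stated where a gene is named for a dose.

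Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 35 arrays, which share 1 estimate of the spread, and each dose was contrasted with vehicle by the moderated test, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The series design names R/maanova at a false discovery rate of 5%; that package was not used here, and limma's test in the same one-way model took its place. A trend over dose rank from 0 to 5, a moderated F test over the 5 dose coefficients and the contrast of 680 with 68 mg/kg came from the same fit. Confidence intervals are 95% intervals of that fit for single genes, not adjusted for the number of genes.

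The 28 gene lists, with 555 of 643 entries measured, were fixed before the data were examined. They covered CAR and PXR, AhR, NRF2 and PPAR-alpha targets, cholesterol, fatty acid and bile acid metabolism, thyroid hormone responsive, cell cycle, p53, acute phase, interferon, circadian, ER stress, heat shock, fasting and male-predominant genes, and markers of pericentral and periportal hepatocytes, macrophages, stellate cells, endothelium, cholangiocytes, lymphocytes, blood, neutrophils, exocrine pancreas, and kidney and adrenal. Each list was tested at each dose with camera at a preset correlation of 0.01, adjusted over the 140 tests, with an estimated correlation and fry beside it. Because all doses share the vehicle rats, correlations between doses are given beside values simulated for unchanged groups.

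The rule for named genes, also fixed before the data were examined, took up to 12 genes that rose and 12 that fell most among those called at each dose whose dose arrays all lay on the same side of the vehicle mean, every called gene of a dose with 10 or fewer, and up to 4 called members of a described list, or where none passed the 2 with the smallest p. Since no gene was called, a further rule was adopted after this had been seen: the first 2 measured members of 12 response lists, in the order the lists were written, gave the 24 response genes. Lists that camera did not call are given by counts. A named gene whose vehicle or dose mean lay below the lowest array median, 4.71, is given by its values in place of a fold, and each list call was repeated without each array of its 2 groups, choices also made after the data had been seen.

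The fit was tested on simulated data with the real means and spread and 50 probe sets changed by each of several known amounts, with independent noise between probe sets. False calls were 11 of 174 at 0.07 mg/kg, 10 of 164 at 0.69, 9 of 166 at 6.88, 14 of 154 at 68 and 8 of 165 at 680 mg/kg. Alternatives were a filter on dim probe sets, quantile normalisation again, median centring, the replicate number as a block, an intensity trend with a robust prior, array weights, an unmoderated analysis of variance, p-values from 100 pooled shuffles of array labels as in R/maanova, 1 probe set per gene, only vehicle and the dose compared, other dose scales with log10 of dose plus 0.01 among them, and leaving out each array. A fit without the 2 arrays farthest from the median array was added after the data had been seen. Permutation tests of single values used 100000 resamples, or 100 splits of the arrays for counts of genes.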

Results

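Liver RNA was profiled from male Harlan Sprague Dawley rats, 7 weeks old at the start, after 5 days of gavage with BTBPE or with its corn oil vehicle alone. BTBPE, 1,2-bis(2,4,6-tribromophenoxy)ethane, is a brominated flame retardant. The highest of the 5 daily doses was 680 mg/kg, the lowest 0.07 mg/kg, with 68, 6.88 and 0.69 mg/kg between them, and tissue was taken from the left lobe on the day after the last dose. Each of the 35 samples was hybridised to 1 rat expression array. There were 6 samples per group, except for 5 at 68 mg/kg. The number of arrays limits the precision of every value. The labels call the samples replications and describe dosing of animals, and each sample is counted here as 1 rat.

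The first comparison asked whether the highest dose, 680 mg/kg, altered liver transcripts relative to vehicle. Measured genes that typically respond to foreign compounds lay near their vehicle levels. Cyp2b1, Cyp2b2 and Cyp2b15, written first in the CAR and PXR list, had no probe set of 1 symbol. They were not analysed as genes, so the values here do not cover them. Cyp3a23-3a1, a drug-metabolising cytochrome P450 induced through the receptor PXR, averaged 12.37 ± 0.21 (log2, SD, n = 6) in vehicle rats and 12.30 ± 0.19 (n = 6) at 680 mg/kg. Its fold value was 0.955, with a 95% confidence interval of 0.820 to 1.11. Cyp1a2, a main target of the aryl hydrocarbon receptor in liver, was 1.04-fold its vehicle level (interval 0.963 to 1.13). Cyp1a1, the classical target of the same receptor, read 4.56 ± 0.23 in vehicle rats and 4.40 ± 0.21 at 680 mg/kg (n = 6 each), a level below the array medians and not shown to be above background.

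The other response genes at 680 mg/kg had similarly small values. Cyp4a1, a fatty acid hydroxylase controlled by PPAR-alpha, was 0.910-fold (interval 0.763 to 1.08), and Cyp4a3 was 0.973-fold (0.844 to 1.12). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, was 1.02-fold (0.874 to 1.20). Sqle and Idi1, enzymes of cholesterol synthesis, were 0.910-fold and 0.979-fold. Fasn and Acaca, enzymes of fatty acid synthesis, were 0.918-fold and 0.929-fold. The thyroid hormone responsive genes Dio1 and Thrsp were 1.03-fold and 0.970-fold. The proliferation gene Top2a was 0.994-fold and Mki67 read 3.87 against 3.86 in vehicle rats, a level not shown to be above background, and the p53 targets Cdkn1a and Mdm2 were 1.12-fold and 0.970-fold. The acute phase genes A2m and Orm1 were 0.787-fold and 1.14-fold, and the stress genes Ddit3 and Atf3 were 0.862-fold and 1.03-fold. Another probe set had the opposite sign for Gclc, Top2a and Mdm2.

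Cyp7a1, the rate-limiting enzyme of classical bile acid synthesis, had the largest SD of these genes over the rats of the whole series. It averaged 10.77 ± 0.83 in vehicle rats and 10.23 ± 0.58 at 680 mg/kg, a 0.687-fold value whose interval of 0.393 to 1.20 was the only 1 of the 24 at this dose that did not exclude a 2-fold change. Cyp8b1, which sets the ratio of bile acid species, was 0.886-fold (0.688 to 1.14). Cyp3a9 was 1.20-fold (0.745 to 1.92). Nqo1, a quinone reductase controlled by NRF2 and the aryl hydrocarbon receptor, averaged 6.79 ± 0.18 in vehicle rats and 7.22 ± 0.82 at 680 mg/kg, 1.35-fold (1.02 to 1.78). That value rested on replicate 6, and without that rat its log2 fold change was 0.10 in place of 0.43. Across the 24 genes 9 were higher and 15 lower, and 23 of the intervals included no change.

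**Figure D1:**
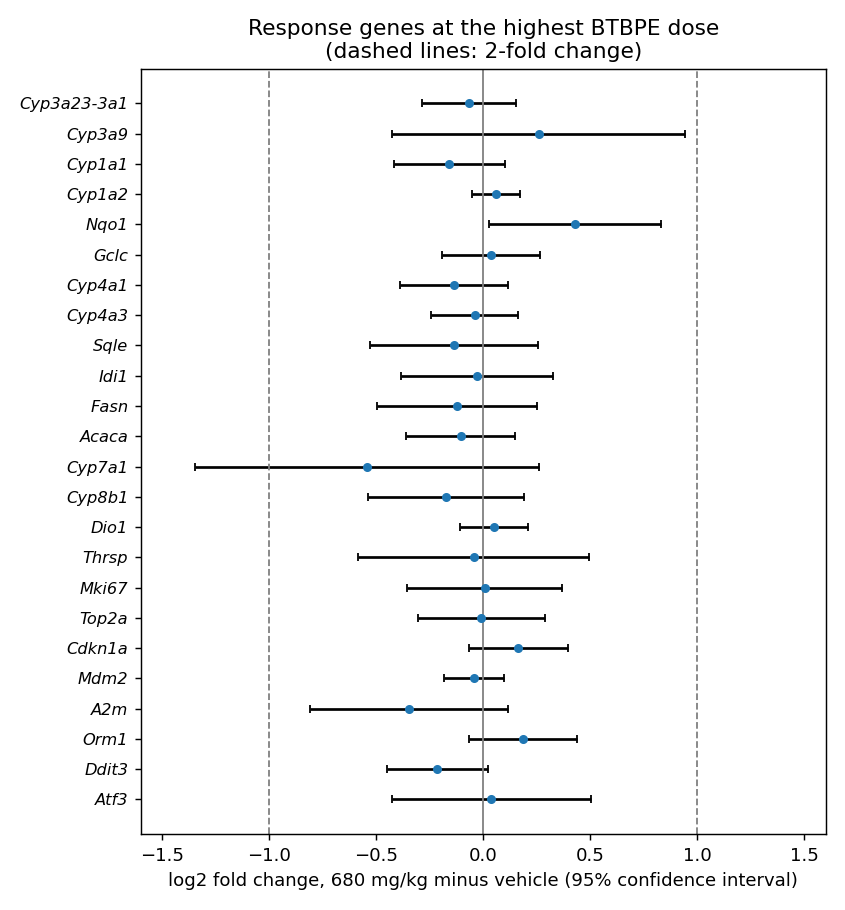
Log2 fold change of 24 response genes at 680 mg/kg BTBPE relative to vehicle (x axis), 1 gene per line, with points for the estimates and bars for 95% confidence intervals from limma (6 rats per group). The intervals of 23 genes include 0 and those of 23 genes lie inside the dashed lines of a 2-fold change, with Cyp7a1 the exception to the second. Cyp1a1 and Mki67 read below the array medians.

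No gene passed the test at 680 mg/kg. limma called 0 of 31042 probe sets, with 1538 at an unadjusted p under 0.05 where chance alone gives 1552, and the smallest adjusted p was 0.988. The unmoderated analysis of variance and the pooled shuffles of array labels also called 0. The 5 genes with the smallest p at this dose, named after their values were seen, were Klhdc7a (1.38-fold), S1pr1 (1.24-fold, a sphingosine-1-phosphate receptor), Asb5 (4.90 in vehicle rats and 4.56 at this dose), Myocd (2.68 in vehicle rats and 3.07 at this dose, near the lower end of the values) and Gadd45b (4.19 and 3.87, below the array medians). A second probe set of S1pr1 had the opposite sign.

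The 28 gene lists were then examined at 680 mg/kg, and 0 members of any list passed over all probe sets. Among the lists of xenobiotic and stress responses, 12 of 23 CAR and PXR targets were higher than vehicle, 7 of 10 AhR targets, 14 of 24 NRF2 targets, 12 of 21 p53 and DNA damage genes, 13 of 27 genes of ER stress and amino acid response and 8 of 15 heat shock genes. Among the metabolic lists, 13 of 37 PPAR-alpha targets were higher, 1 of 21 genes of cholesterol synthesis and uptake, 6 of 22 of fatty acid and triglyceride synthesis, 4 of 20 of bile acid synthesis and transport and 9 of 15 thyroid hormone responsive genes. Of the remaining lists, 14 of 41 cell cycle genes, 12 of 31 acute phase genes, 5 of 23 interferon response genes, 10 of 19 circadian clock genes and 11 of 17 male-predominant genes were higher. None of these was called by camera. The mean difference of the cholesterol list was -0.06, but -0.16 without vehicle replicate 4 and 0.01 without replicate 5 at 680 mg/kg, and the list was called without vehicle replicate 4 or 6 or replicate 2 or 3 at 680 mg/kg.

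Markers of cell types were counted in the same way at 680 mg/kg. Pericentral hepatocyte genes were higher for 8 of 14 and periportal genes for 8 of 17. Kupffer and macrophage genes were higher for 2 of 19, lymphocyte genes for 4 of 21, stellate cell and fibroblast genes for 11 of 22, endothelial genes for 12 of 18 and cholangiocyte genes for 5 of 13. Markers of blood were higher for 6 of 11, of neutrophils for 6 of 9, of exocrine pancreas for 8 of 17 and of kidney and adrenal for 6 of 10. None of these 11 lists was called by camera at this dose.

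Camera called 1 of the 28 lists at 680 mg/kg, that of fasting and gluconeogenesis, with 13 of 18 members lower. Its adjusted p was 0.0364 with the preset correlation, and it was not called at an adjusted p of 0.401 with an estimated correlation. Its members with the smallest p were Lpin2, a phosphatidate phosphatase, at 0.797-fold (interval 0.675 to 0.942), and Pc, the pyruvate carboxylase that opens gluconeogenesis, at 0.868-fold (0.777 to 0.971). Both lay below the vehicle mean in 6 of 6 rats. The list was also not called without vehicle replicate 2, 3 or 5 or without replicate 2 or 6 at this dose. Among CAR and PXR targets, Gadd45b was the only 1 of 23 members to pass when adjusted over the list alone (limma adjusted p = 0.00641), against an adjusted p of 0.988 over all probe sets.

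At 68 mg/kg the response genes again lay near vehicle levels, between 0.861-fold and 1.38-fold for those read above the array medians. Cyp1a1 read 4.24 ± 0.35 (n = 5), a level not shown to be above background, Cyp1a2 was 0.976-fold (0.899 to 1.06) and Cyp3a23-3a1 was 1.03-fold (0.876 to 1.21). limma called 0 of 31042 probe sets, with 1205 at an unadjusted p under 0.05, and the other 2 tests of the same contrast also called 0. The smallest adjusted p was 0.822.

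The largest list median of the whole series stood at 68 mg/kg, in macrophage markers. Of the 19 Kupffer and macrophage genes 17 were lower, with a median log2 fold change of -0.29. Replicates 2 and 5 carried this, with mean deviations of the list from all rats of -0.55 and -0.53, while replicates 1, 3 and 4 stood at 0.08, 0.22 and 0.12. The same 2 rats were low in interferon response genes (-0.71 and -0.63), which were lower for 18 of 23 at this dose and not called by camera. Cd163, a scavenger receptor of resident macrophages, averaged 6.59 ± 0.26 in vehicle rats (n = 6) and 6.22 ± 0.22 (n = 5), 0.769-fold (interval 0.605 to 0.976). Cd14 went the other way, at 1.23-fold (0.994 to 1.52). Sinusoidal and vascular endothelial genes were lower for 14 of 18, among them Stab2, a scavenger receptor of sinusoidal endothelium, at 0.865-fold and Kdr, a receptor for vascular endothelial growth factor, at 0.896-fold. Camera called both lists with the preset correlation (adjusted p = 3.35e-05 and 0.0161), and neither with an estimated correlation (adjusted p = 0.976 for both). Without replicate 2 the macrophage list was not called and its mean difference was -0.12 in place of -0.23, and without replicate 5 the endothelial list was not called and its mean difference was -0.05 in place of -0.08. Adjusted over the list alone, Bhlhe41 of the clock list, Cftr of the cholangiocyte list and Prss2 of the exocrine pancreas list passed (limma adjusted p = 0.0188, 0.0356 and 0.00129), and 0 genes passed over all probe sets. Their vehicle means of 3.14, 3.18 and 2.54 lie near the lower end of the values and were not shown to be above background.

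At 6.88 mg/kg 5 lists were placed lower by camera with the preset correlation, more than at any other dose. With an estimated correlation none was called, at adjusted p = 0.976 for cell cycle, cholesterol and endothelium, 0.841 for CAR and PXR and 0.858 for NRF2. Cell cycle genes were lower for 36 of 41, with Bub1, a spindle checkpoint kinase, at 3.52 against 3.97 in vehicle rats, and Aurka, a mitotic kinase, at 4.64 against 4.96, levels not shown to be above background. Vehicle replicate 2 stood high in this list, and without it the mean difference was -0.09 in place of -0.18. Genes of cholesterol synthesis and uptake were lower for 19 of 21, with Dhcr7 at 0.791-fold and Fdft1 at 0.887-fold. CAR and PXR targets were lower for 18 of 23, with the glutathione transferase Gsta3 at 0.657-fold (0.487 to 0.887) and the efflux pump Abcb1a at 0.863-fold. NRF2 targets were lower for 19 of 24, with Me1 at 0.834-fold and Gstp1 at 0.915-fold, and endothelial genes were lower for 14 of 18, with Ptprb at 0.909-fold and Fcgr2b at 0.846-fold. A second probe set of Ptprb had the opposite sign.

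The preset adjusted p at 6.88 mg/kg was 1.65e-06 for cell cycle, 0.0106 for cholesterol, 0.0319 for CAR and PXR, 0.0344 for NRF2 and 0.0108 for endothelium. With an estimated correlation the adjusted p values were 0.841 or more. Only the cell cycle list was called with any 1 of the 12 rats left out. The CAR and PXR list was lost without vehicle replicate 1, 2 or 3 or replicate 2, 3, 4 or 5 at this dose, and the NRF2 list without vehicle replicate 2, 3, 4 or 5 or replicate 4, 5 or 6. The cholesterol list was lost without vehicle replicate 1, 2, 3 or 5, with a mean difference of -0.07 without vehicle replicate 3 and -0.21 without vehicle replicate 4 in place of -0.12, and the endothelial list without replicate 2, 5 or 6. limma called 0 of 31042 probe sets, with 1438 at an unadjusted p under 0.05, the other 2 tests called 0, and the smallest adjusted p was 0.617. No member passed when adjusted over the list alone in these 5 lists. The response genes read above the array medians ranged from 0.793-fold for Cyp7a1 to 1.08-fold for Cdkn1a, and Cyp4a1 was 0.820-fold (interval 0.688 to 0.977).

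At 0.69 mg/kg PPAR-alpha targets were lower for 32 of 37, with a median log2 fold change of -0.11. Hadhb, a subunit of the mitochondrial trifunctional protein of fatty acid oxidation, averaged 11.22 ± 0.09 in vehicle rats and 11.05 ± 0.06 (SD, n = 6 each), 0.890-fold (interval 0.827 to 0.958). Crat, carnitine acetyltransferase, was 0.860-fold (0.771 to 0.958). Both lay below the vehicle mean in 6 of 6 rats. Cell cycle genes were higher for 31 of 41, with the kinase Melk at 3.20 against 2.96 in vehicle rats, and cyclin Ccnb1 at 4.87 against 4.52, levels not shown to be above background. Camera called PPAR-alpha targets lower (adjusted p = 1.29e-07) and cell cycle genes higher (adjusted p = 0.0111) with the preset correlation, and neither with an estimated correlation (adjusted p = 0.401 and 0.976). The cell cycle shift rested on replicate 4, without which the mean difference of the list was 0.01 in place of 0.07, and it was also not called without replicate 1 or vehicle replicate 3, 4 or 5. Without vehicle replicate 2 that difference was 0.15. The PPAR-alpha list was called with any 1 of the 12 rats left out. Kupffer and macrophage genes were lower for 17 of 19 and endothelial genes for 16 of 18 at this dose, and camera called neither. limma called 0 of 31042 probe sets, with 981 at an unadjusted p under 0.05, the other 2 tests called 0, and the smallest adjusted p was 1.00. Prss2 passed when adjusted over its list alone (limma adjusted p = 0.00969), at 2.30 against 2.54 in vehicle rats, a level not shown to be above background, and 0 genes passed over all probe sets.

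At the lowest dose, 0.07 mg/kg, PPAR-alpha targets were lower for 27 of 37, Kupffer and macrophage genes for 17 of 19 and endothelial genes for 16 of 18. The PPAR-alpha members with the smallest p went both ways, Cpt1b at 1.15-fold (interval 1.03 to 1.29) and Acaa2 at 0.842-fold (0.718 to 0.988), and a second probe set of Acaa2 had the opposite sign. Among macrophage genes Lyz2, a lysozyme, was 0.746-fold (0.539 to 1.03) and Laptm5 was 0.930-fold. The endothelial genes Ptprb, a receptor phosphatase, and Flt4, a receptor for vascular endothelial growth factors, were 0.847-fold and, at a level below the array medians, 4.22 against 4.43. Macrophage genes were low in replicates 1, 3 and 6 (-0.28, -0.22 and -0.19, as deviations of the list from all rats) and endothelial genes in replicates 1 and 6 (-0.25 and -0.12). Replicates 1 and 6 had the highest Actb 3 prime minus 5 prime values of this group, 1.28 and 1.26, and replicate 3 read 1.13. Camera called the 3 lists with the preset correlation (adjusted p = 0.0108, 0.00210 and 0.00168) and none with an estimated correlation (adjusted p = 0.924, 0.976 and 0.858). The PPAR-alpha list was not called without vehicle replicate 6 or replicate 6 at this dose. Without replicate 1 neither of the other 2 lists was called, with mean differences of -0.12 in place of -0.16 for macrophage genes and -0.04 in place of -0.09 for endothelial genes. limma called 0 of 31042 probe sets, with 1130 at an unadjusted p under 0.05, the other 2 tests called 0, and the smallest adjusted p was 0.651. Prss2, at the same low level, passed when adjusted over its list alone (limma adjusted p = 0.00895), and 0 genes passed over all probe sets.

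**Figure D2:**
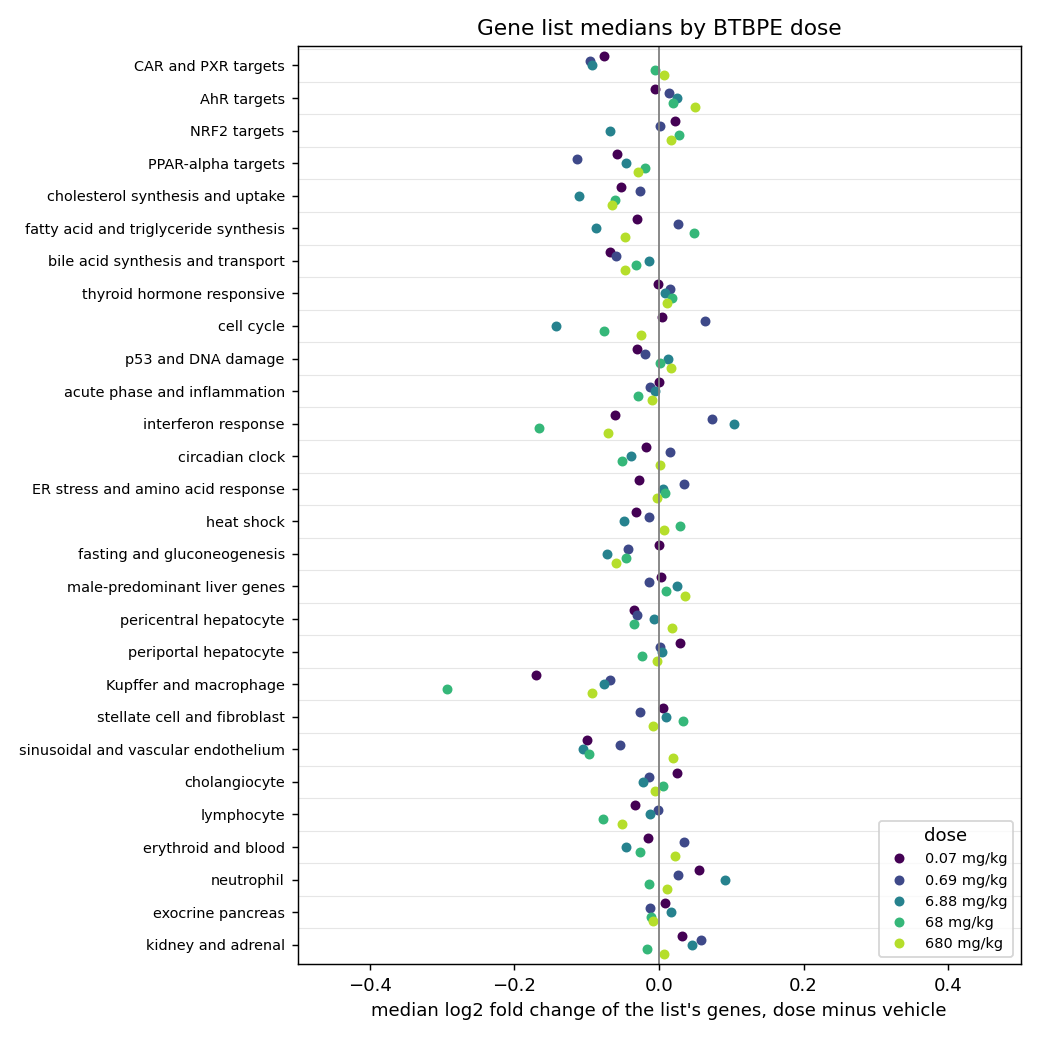
Median log2 fold change of the measured genes of each of 28 lists (x axis) at each BTBPE dose relative to vehicle, with 1 point per list and dose, coloured by dose. The medians lie between -0.29, for Kupffer and macrophage genes at 68 mg/kg, and 0.10, for interferon response genes at 6.88 mg/kg.

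Across all doses camera called 13 of 140 pairs of list and dose with the preset correlation, 12 lower and 1 higher. All doses share the vehicle rats, so results in the same direction at several doses are not independent. It called 0 of 140 with an estimated correlation, where the smallest adjusted p was 0.401, and fry called 0, with a smallest adjusted p of 0.517. No list was called at every dose, and 11 of the 13 calls were lost when 1 array of the compared groups was left out. Camera placed PPAR-alpha targets lower at 0.07 and 0.69 mg/kg and did not call them at the 3 higher doses, and it placed cell cycle genes higher at 0.69 mg/kg and lower at 6.88 mg/kg.

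A graded response over the 6 groups was tested next. The gene with the smallest p for a trend over dose rank was Myocd, a low-expressed transcript that averaged 2.68 ± 0.22 in vehicle rats and 3.07 ± 0.11 (SD, n = 6 each) at 680 mg/kg, with a limma adjusted p of 0.449 for the trend. Zfp354a, a zinc finger gene named here after its values were seen, differed more from vehicle at 680 mg/kg than Myocd did. It averaged 7.78 ± 0.62 in vehicle rats, 7.50 ± 0.68 at 0.07 mg/kg, 6.94 ± 0.33 at 0.69 mg/kg, 7.10 ± 0.62 at 6.88 mg/kg, 6.94 ± 0.50 at 68 mg/kg and 6.68 ± 0.21 at 680 mg/kg. Its value at 680 mg/kg was 0.466-fold (interval 0.315 to 0.690), below the vehicle mean in 6 of 6 rats, with a limma adjusted p of 0.988 at this dose and 0.954 for the trend. limma called 0 of 31042 probe sets for the trend, with 1549 at an unadjusted p under 0.05, and 0 for a difference between any groups, with 1194.

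**Figure D3:**
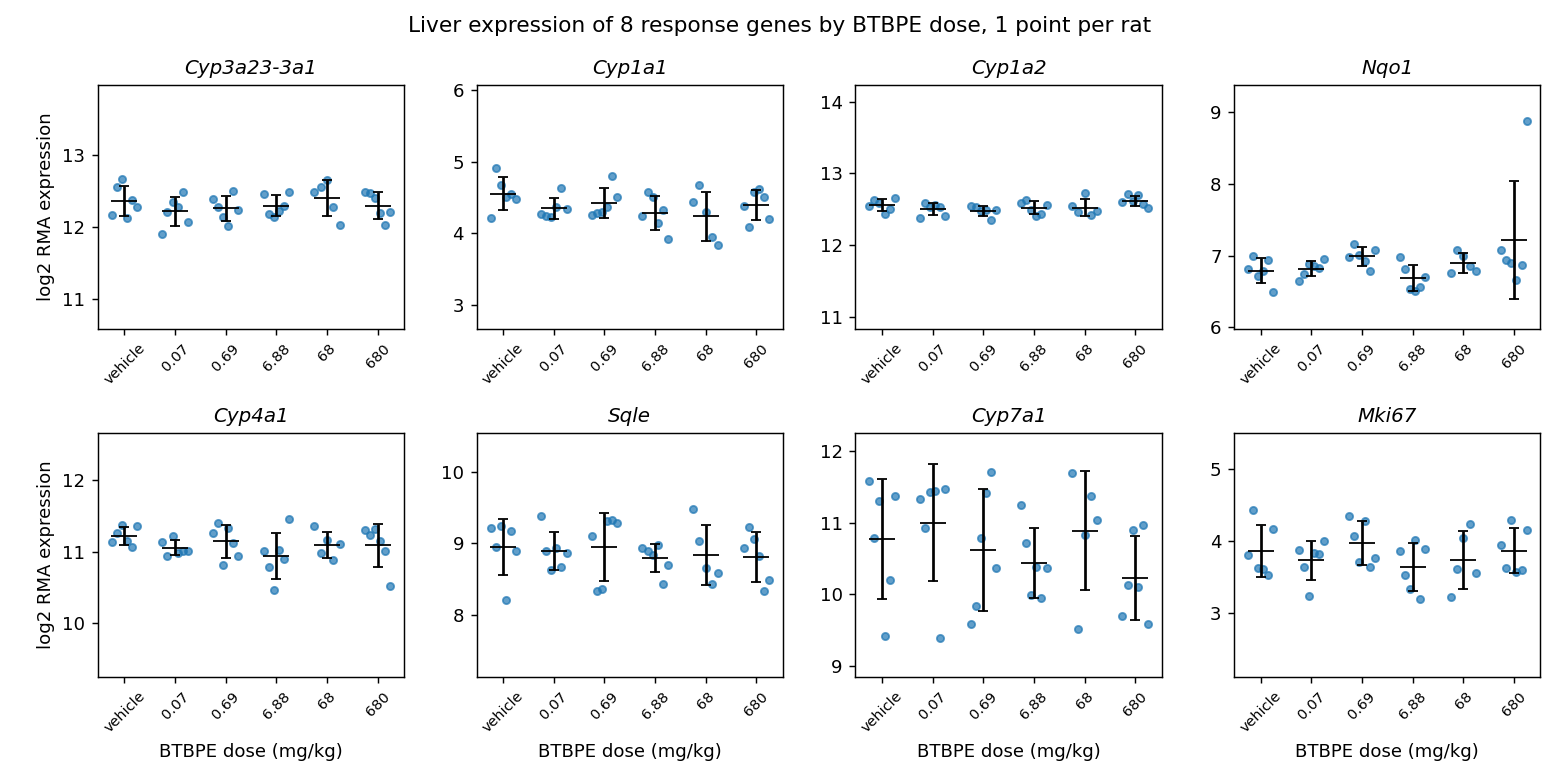
Log2 RMA expression (y axis, the same span of 3.4 units in each panel) of 8 response genes by BTBPE dose in mg/kg (x axis), with 1 point per rat, dashes for group means and bars for SD (6 rats per group, 5 at 68 mg/kg). Group means stay within the spread between rats, Cyp7a1 is widely spread in every group, and 1 rat at 680 mg/kg lies at 8.87 for Nqo1.

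The 2 highest doses were also compared with each other. limma called 0 of 31042 probe sets between 680 and 68 mg/kg, with 1332 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. The fold changes of different doses correlated across probe sets, which are not independent replicates, at r = 0.41 to 0.49. Because all doses share the vehicle rats, unchanged groups simulated against the same vehicle gave mean r of 0.46 to 0.49. With the vehicle rats split into separate sets for the 2 doses the mean r was -0.09 to 0.02. The covariances were 0.00341 to 0.00480, beside simulated means of 0.00471 to 0.00509.

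The precision of these comparisons bounds what was detectable. The median 95% confidence interval of a probe set reached 0.17 log2 units either side, 1.12-fold, at 680 mg/kg, and 0.18 at 68 mg/kg. The interval of a single probe set excluded a 2-fold change for 99.7% of probe sets at both 680 and 68 mg/kg, and a 1.5-fold change for 98.2% and 98.1%. When known changes were added to simulated data for the 680 mg/kg comparison, 13 of 50 probe sets changed by 0.25 log2 units were recovered, 45 of 50 changed by 0.5, 49 of 50 changed by 1 and 50 of 50 changed by 2. For the 68 mg/kg comparison the recovered numbers were 8, 34, 49 and 49 of 50. Changes of about 1.19-fold in single genes were thus mostly not detectable with these arrays. All sizes of change were added together, and the 165 calls of the 680 mg/kg simulation loosen the adjusted threshold. A gene changed alone would need a smaller p, so the recovered numbers overstate recovery where few genes change.

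The arrays resembled each other closely. Pairwise correlations across probe sets lay between 0.991 and 0.996, and no pair of arrays held identical values. The Actb signal from 3 prime minus 5 prime probe sets, a sign of RNA quality, averaged 1.12 ± 0.08 in vehicle rats (n = 6) and 1.15 ± 0.08 at 680 mg/kg (n = 6), with 1.23 ± 0.09 at 6.88 mg/kg (n = 6) the highest, and a permutation test between the 6 groups gave p = 0.186. The same measure of Gapdh was highest at 6.88 mg/kg, at 0.06 ± 0.07, with a permutation p of 0.0559. At 6.88 mg/kg, the dose with the most lists placed lower, both signs thus had their highest mean. The arrays farthest from the median array were replicate 5 at 0.07 mg/kg and replicate 2 at 6.88 mg/kg.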

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

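The tests of Ugt2b in its pair of probe sets, by dose and for inheritance, and the tests of the macrophage pattern in vehicle rats and by share of hepatocytes, were chosen after those results were seen. Dixon's gap test for a single rat far from its group was run on 65 named genes and array measures in each of the 6 groups. These 390 tests flagged 28 values, where chance gives about 19.5. The same rat could be flagged more than once, at most 4 times, and the tests share the same rats, so they are not independent. Of the 28, 13 lay in genes chosen after their values were seen. The other genes and measures gave 15 in 306 tests, where chance gives about 15.3.

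Ugt2b, a glucuronosyltransferase gene, was far lower in 3 rats. Its brighter probe set read 4.34 in vehicle replicate 3, 4.57 in replicate 5 at 0.69 mg/kg and 4.97 in replicate 2 at 6.88 mg/kg, against 12.2 to 12.8 in the other rats. Low rats included 1 in the vehicle group, which argues against the dose, the values were low in 2 of 2 probe sets annotated to it, and at most 1 probe set of other genes on these 3 arrays lay over 4 log2 units from the median of the other arrays, which argues against a faulty probe set and a poor array. In the dimmer probe set a gap of 0.41 parted the other rats, 18 at 8.23 to 8.73 and 14 at 9.14 to 9.58. In the brighter probe set the same 18 rats read 12.24 to 12.54 and the same 14 read 12.63 to 12.84, a narrower gap that was not tested. For the dimmer probe set the following tests were run. Inner gaps this wide had p = 0.0170 in normal simulations, and counts of 3, 18 and 14 an exact Hardy-Weinberg p of 0.706. Gaps at the outermost values were not counted in those simulations, so they do not cover a gap anywhere. An inherited loss in this outbred stock is a candidate explanation that stays open, since whether the 2 probe sets detect 1 gene or several of the family was not tested, and a loss of this kind in a related glucuronosyltransferase is known in Wistar rats.

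Macrophage, lymphocyte and interferon genes varied together among rats of one dose. Over deviations from the dose means in 35 rats, the macrophage list correlated with the interferon list at r = 0.88 (Spearman 0.85, permutation p = 1e-05 for both, the smallest the test can give; adjusted over 12 relations, 3e-05 and 4e-05; r = 0.86 without the 2 farthest rats) and with the lymphocyte list at r = 0.80 (Spearman 0.81, p = 1e-05 for both, adjusted 3e-05 and 4e-05, 0.75 without 2). A varying share of hepatocytes would move the markers of other cell types alike. Endothelial genes went with the macrophage list (r = 0.66, interval 0.39 to 0.82, Spearman 0.65, permutation p = 1e-04 and 0.000140, adjusted 0.000240 and 0.000336, 0.61 without 2), and stellate cell genes weakly (r = 0.24, interval -0.14 to 0.55, Spearman 0.17, p = 0.218 and 0.381, adjusted 0.238 and 0.416, 0.22 without 2). Cholangiocyte genes did not go with it (r = -0.33, interval -0.62 to 0.03, Spearman -0.36, p = 0.0275 and 0.0430, adjusted 0.0366 and 0.0573, -0.31 without 2). How far the cholangiocyte list measures these cells was not tested, and its member Cftr averaged 3.18 in vehicle rats, not shown to be above background. These values therefore do not decide whether that share is the whole cause, and a joint change of macrophages and endothelium stays open. RNA quality stays open, since the list followed the Actb 3 prime minus 5 prime value at r = -0.59 (Spearman -0.59, permutation p = 0.000330 and 0.000290, adjusted 0.000660 and 0.000580, -0.54 without 2). A shift of dose means was subtracted and cannot produce the pattern, but a part of BTBPE in the spread between rats is not decided. In the 6 vehicle rats alone the macrophage and interferon lists gave r = 0.91 (exact permutation p = 0.0444), and r = 0.23 without replicate 3. With all rats of each dosed group, r was 0.63 at 0.07 mg/kg, 0.89 at 0.69, 0.98 at 6.88, 0.97 at 68 and 0.90 at 680 mg/kg. Without the farthest rat of each, it was 0.38 at 0.07 mg/kg, 0.88 at 0.69, 0.97 at 6.88, 0.95 at 68 and 0.86 at 680 mg/kg. Whether r differed between groups was not tested.

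Bcl6, Socs2, Cish and Onecut1 varied widely among rats of one dose, which raised the phase of the growth hormone pulse at death as a hypothesis. Single rats far from their group were Bcl6 at 5.81 in replicate 5 at 0.07 mg/kg (others 9.21 to 10.10), Socs2 at 6.22 in replicate 5 at 680 mg/kg (others 7.98 to 8.45) and Cish at 6.76 in replicate 6 at 6.88 mg/kg (others 4.51 to 4.93). Bcl6 ran against Socs2 (r = -0.85, Spearman -0.83, permutation p = 1e-05 and 2e-05, adjusted 3e-05 and 6e-05, -0.81 without the 2 farthest rats), against Onecut1 (r = -0.86, Spearman -0.83, p = 1e-05 for both, adjusted 3e-05 and 4e-05, -0.84 without 2) and against Cish (r = -0.59, Spearman -0.58, p = 0.000890 and 0.000790, adjusted 0.00153 and 0.00135, -0.56 without 2), which go with that phase but were chosen for their spread. Bcl6 did not run against the mean of the growth hormone targets Igf1, Igfals and Socs3 (r = -0.0275, interval -0.38 to 0.34, Spearman -0.08, permutation p = 0.890 and 0.692, adjusted 0.890 and 0.692, -0.05 without 2). The prediction made for that phase was thus not met in these genes. Whether their transcripts follow single pulses was not tested, so these values do not decide the phase. RNA quality (r = 0.46 with Actb, Spearman 0.49, permutation p = 0.00722 and 0.00449, adjusted 0.0108 and 0.00673, 0.43 without 2) and other cell types (r = -0.30 with the macrophage list, Spearman -0.33, p = 0.110 and 0.0856, adjusted 0.132 and 0.103, -0.25 without 2) are not decided by these values, and dose was not tested for this pattern.

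The remaining single rats far from their group are given as values, lowest and highest of the others in brackets. Nqo1 read 8.87 in replicate 6 at 680 mg/kg (6.66 to 7.08). In replicate 5 at 0.07 mg/kg, Cyp7a1 read 9.39 (10.93 to 11.47), Cyp1a1 4.63 (4.23 to 4.36) and Atf3 5.45 (4.71 to 4.89). In replicate 5 at 0.69 mg/kg, Cyp1a2 read 12.34 (12.48 to 12.54), Cd163 5.47 (6.44 to 6.70) and Kdr 9.04 (9.35 to 9.50). In vehicle replicate 4, Sqle read 8.21 (8.89 to 9.24) and Cyp8b1 10.08 (10.60 to 10.83). At 68 mg/kg Cyp8b1 read 9.87 in replicate 2 (10.57 to 10.80), Top2a 5.06 in replicate 3 (4.61 to 4.69) and Fcgr2b 8.71 in replicate 5 (9.27 to 9.42). In replicate 6 at 6.88 mg/kg, Melk read 2.73 (2.92 to 2.99) and Lpin2 6.58 (6.87 to 7.01). In replicate 4 at 0.69 mg/kg, Ccnb1 read 5.44 (4.62 to 4.88) and Zfp354a 7.58 (6.72 to 6.94). Cftr read 2.93 in replicate 3 at 0.07 mg/kg (3.16 to 3.27) and 2.92 in replicate 6 at 0.69 mg/kg (3.08 to 3.17). S1pr1 read 11.11 in replicate 6 at 0.07 mg/kg (10.79 to 10.88), and Asb5 5.18 in vehicle replicate 6 (4.78 to 4.92). At 680 mg/kg Gadd45b read 3.64 in replicate 2 (3.87 to 3.98) and Bhlhe41 3.13 in replicate 4 (2.76 to 2.90).

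The arrays were split in 100 ways, the real one included. For the 8 counts of called probe sets this decides nothing, since the real count was 0 and all 100 splits reach it; the highest of the other splits called 1 at 0.07 mg/kg, 0 at 0.69, 1 at 6.88, 2 at 68 and 1 at 680 mg/kg, 28 between 680 and 68 mg/kg, 56 for the trend and 2 for any groups. Chance could not be excluded for the counts at an unadjusted p under 0.05 or for the list calls. At an unadjusted p under 0.05, as many probe sets were reached in 92 splits at 0.07 mg/kg (real 1130, highest other 2706), 74 at 0.69 (981, 2068), 56 at 6.88 (1438, 4565), 87 at 68 (1205, 2219) and 29 at 680 mg/kg (1538, 2507). As many lists as the real 13 were called in 93 splits, and the highest of the others called 39. The splits with 4565 probe sets and with 39 lists gave several times the real counts. Whether this reflects a structure of the samples or genes that vary together between rats was not tested.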

How the results depend on the processing

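The fit without the 2 arrays farthest from the median array was chosen after the data were seen. All 8 counts of called probe sets were 0 under every alternative run for them and with each array left out in turn, while the counts at an unadjusted p under 0.05 ran from 716 to 1856 at 680 mg/kg, the lowest where fewer probe sets were tested. Of the 13 list calls, 0 held with an estimated correlation and 0 with fry. The estimated correlation was 0.645 for macrophage, 0.618 for cholesterol, 0.417 for cell cycle, 0.257 for endothelial and 0.109 for PPAR-alpha genes. It was 0.0856 for NRF2 and 0.0767 for CAR and PXR targets, all above the preset 0.01. Fasting genes had 0.00762, below the preset, so a higher correlation within that list cannot account for the loss of its call. Its unadjusted camera p at 680 mg/kg moved little, from 0.00338 with the preset to 0.00573 with the estimated correlation. Its adjusted camera p went from 0.0364 to 0.401. The adjustment is shared by all lists and doses, and the p values of the other called lists rose with their higher correlations. That call was thus lost through the shared adjustment. The cause was not tested for fry. Averaging the probe sets of a gene gave 16 list calls, 12 of them shared, array weights 18 (12 shared) and leaving out the 2 farthest arrays 18 (11 shared). Leaving out single arrays gave 10 to 27 list calls, with 27 without vehicle replicate 4 and 20 without vehicle replicate 6. The replicate numbers did not pair the samples, since deviations of same-numbered rats correlated at a median of -0.02 (-0.29 to 0.24) and 8 of 85 pairs were over 0.1. With the replicate number as a block 0 probe sets and 14 lists were called, 13 of them shared. The log2 fold changes of the 24 response genes at 680 mg/kg changed sign for 0 to 4 genes by setting, none of them called, and moved by at most 0.33, without replicate 6 at 680 mg/kg. Dim probe sets limit what the arrays can show, since their signals lie near background.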

Other observations

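The genes in these paragraphs were named after their values were seen. Rats given the same dose differed widely in a few liver transcripts. The median SD within a dose over 14217 genes was 0.14 log2 units, and 10 genes exceeded 1. After Ugt2b (SD 2.35) and Bcl6 (1.64), the most variable were RT1-Bb, a class II histocompatibility gene (1.41), Ubd, an interferon-inducible ubiquitin-like gene (1.38), Ephx2, the soluble epoxide hydrolase (1.22), Lum, a matrix proteoglycan (1.22), and Cdh17, a cadherin (1.15). The interferon-inducible genes Mx2 (0.88), Rtp4 (0.80), Mx1 (0.72), Oas1a (0.71) and Usp18 (0.70) and the feeding-sensitive genes Igfbp1 (0.82) and Fgf21 (0.84) were also among the 40 most variable genes.

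Among the gene lists the interferon response varied most between rats, with an SD of 0.36 log2 units over 35 rats and a 2.61-fold range from the lowest to the highest rat. Kupffer and macrophage genes had a 2.03-fold range, stellate cell genes 1.80-fold, cell cycle genes 1.70-fold, and genes of cholesterol and of fatty acid synthesis 1.64-fold each. Periportal hepatocyte genes had a 1.25-fold range and exocrine pancreas genes 1.21-fold. In permutation tests of the 28 list means between dose groups, AhR targets had the smallest p (0.0470, adjusted 0.972).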
